A study of Mus musculus with 4 samples.

How the data were processed

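Single cells of a mouse embryonic stem cell line with a tagged BRG1 were profiled by 10x droplet sequencing with the V2 chemistry and Illumina sequencing, per the series' design text. The 4 libraries were wild-type mesoderm, Brm knockout mesoderm, wild-type cardiac stage and Brm knockout cardiac stage, with 1 library in each group. Reads were processed with Cell Ranger and Seurat against the mm9 build, per the submitters' processing notes, and their versions are not given in the sources used here. Cell filters, the treatment of doublets, the clustering settings and which libraries entered the clusters are not given in the sources used here either. Reads, count matrices and a map from cells to libraries were not used here. Depth and cell numbers per library are therefore unknown, and no counting interval was made.

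The authors deposited a table of marker genes in which each entry sets 1 numbered cluster against all other cells, per the file header. Its fold changes are natural log values by the authors' deposited header name, which Seurat uses for natural logs. The base was tested on 4 genes for which the deposited fold changes and the solved cluster sizes must account for all of the expression, and the natural base held for 4 of 4 while base 2 and base 10 held for none. Folds in the text are the exponential of the deposited value. The constant that the authors added before taking logs is not given in the sources used here, so folds of weakly expressed genes may be understated. The authors' deposited share of cells with a gene is given inside and outside each cluster, and is printed here as a percent. The authors' deposited p-values compare cells, and cells are not replicates, so they were used only as a filter in 1 alternative. The adjusted p-value was the p-value multiplied by 37991. The smallest absolute natural log fold change in the table was 0.50, and the larger share of cells in each entry was at least 25.1%, so a gene that is not listed may still differ by less than these thresholds. Of the 1197 gene names, 1140 matched a current symbol and 1194 a current or older one, and 3 names carried a version suffix.

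Genes listed for each cluster were counted by direction. For 20 gene lists fixed before the data were examined, members listed higher or lower in each cluster were counted. Each count was set beside 10000 random lists of the same size from all genes in the table (seed 1), as the percent of random lists with a smaller count. A list was called above the 95th percentile. The lists were pluripotency, primitive streak and nascent mesoderm, cardiac progenitor, cardiomyocyte contractile, smooth muscle and fibroblast, endothelial and blood, neural progenitor, neuron, neural crest, endoderm, epithelial and surface ectoderm, S phase, G2 and M phase, glycolysis and hypoxia, stress and immediate early genes, BMP with TGF-beta and Notch signalling, Wnt and retinoic acid signalling, Hox genes, the BAF complex and imprinted genes. A cluster was called like a cell type where a cell type list with at least 3 listed members was called and its leading genes did not go against it.

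Relative sizes of clusters were solved by least squares. The share of all cells that detect a gene must come out the same from each cluster that lists it, and 407 genes were listed for 2 or more clusters. Intervals of 95% came from 1000 redraws of genes. The sizes summed to 100.002%, with a residual SD of 0.0228 percentage points. The share of detecting cells that a cluster holds was worked out from these sizes. Levels in 2 clusters were set side by side for genes listed in both, and called different from 0.5 on the natural log scale. Genes listed for only 1 of the 2 were not compared, so such a comparison can miss differences. Beside each overlap of 2 lists stands the overlap of independent lists, the product of their lengths divided by 1197.

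Genes were named by a rule fixed before the data were examined. It takes the 5 genes with the highest and the 3 with the lowest log fold change of each cluster, leaving out predicted gene models and clones. It adds the 4 members with the largest absolute change of each called list. Other genes are given as chosen after their values were seen. The text prints some of the genes that the rule takes and not all of them, and 1 gene is not reported here. The planned contrasts of genotype and stage were not made, because the clusters carry numbers only. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The steps were tested on simulated data of 15 clusters. The largest error of a size was 0.0148 percentage points over 2044 genes, a planted list reached percentile 100, and 4.67% of 300 unplanted combinations passed the threshold over 1910 genes. Alternatives were stricter thresholds of fold, p-value and detection, genes listed higher in a single cluster, matched random lists, a background without ribosomal, mitochondrial and predicted genes, another ranking and 2 other solutions of size. A reference without cluster 2, and leaving out the genes higher in cluster 2, were chosen after seeing the data. No coordinates are given, because the reference at hand is of another build.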

Results

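Mouse embryonic stem cells carrying a triple FLAG tag on BRG1 were taken through a directed cardiac differentiation, and single cells were profiled at a mesoderm stage and a cardiac stage. The wild-type line was set beside a line lacking Brm, which Smarca2 encodes and which is an alternative ATPase to BRG1 (Smarca4) in the BAF chromatin remodelling complex. The series held 4 libraries, 1 for each genotype and stage, so no value below has a replicate and no test between groups was made. The values came from the authors' deposited table of marker genes, which sets each of 15 numbered cell clusters against all other cells and holds 2212 entries for 1197 genes. Its columns name no library, and which libraries' cells entered it is not given in the sources used here. The name it was deposited under mentions only the Brm knockout, so it may not hold cells of all 4 libraries. The contrasts of genotype and of stage were therefore not made, and clusters were compared by number. Cell numbers and depth are unknown. The clusters were formed from the same expression values, so their marker genes define them and are not independent findings.

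The knocked-out gene was looked up first. Smarca2 and Smarca4 were listed for 0 of the 15 clusters in the authors' deposited table, which shows only that neither passed the table's thresholds in any cluster and does not check the genotype labels. Of the 27 genes on the BAF complex list, 3 were in the table, and all 3 were lower in cluster 2. Smarcc1, a core subunit of the complex, was 2.19-fold lower there and was detected in 18% of cells inside against 49.5% outside, in the authors' deposited table. Smarcb1, another core subunit, was 1.73-fold lower, and Actb, which is also the main cytoskeletal actin, was 2.07-fold lower in the authors' deposited table. Actb was also listed higher in cluster 7 and Smarcc1 lower in cluster 14, counts of 1 at percentiles 90.4 and 74.2. The cluster 2 count of 3 lay at percentile 98.4 of 10000 random lists of the same size, and fell to percentile 91.6 with random lists matched on detection. Each list count given below lay above the 95th percentile of random lists, unless the text says otherwise.

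The relative size of each cluster was solved from the shares of cells that detected each gene inside and outside the clusters. Cluster 0 was the largest, with 15.5% of cells, followed by cluster 1 with 13.3%, cluster 2 with 12.6% and cluster 3 with 10.4%. Clusters 4 to 8 held between 6.04% and 8.61% each, and clusters 9 and 10 held 3.24% and 2.93%. The smallest were cluster 11 with 1.86% (95% interval 1.80 to 1.91 over redrawn genes), cluster 12 with 1.60%, cluster 13 with 0.497% (0.449 to 0.541) and cluster 14 with 0.291% (0.271 to 0.310). These intervals cover the choice of genes and not the sampling of cells. The table held 1305 higher and 907 lower entries, and 790 genes were listed for a single cluster. Clusters 14 and 2 had the most higher genes, 314 and 272, and cluster 11 had the fewest, 10.

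**Figure D1:**
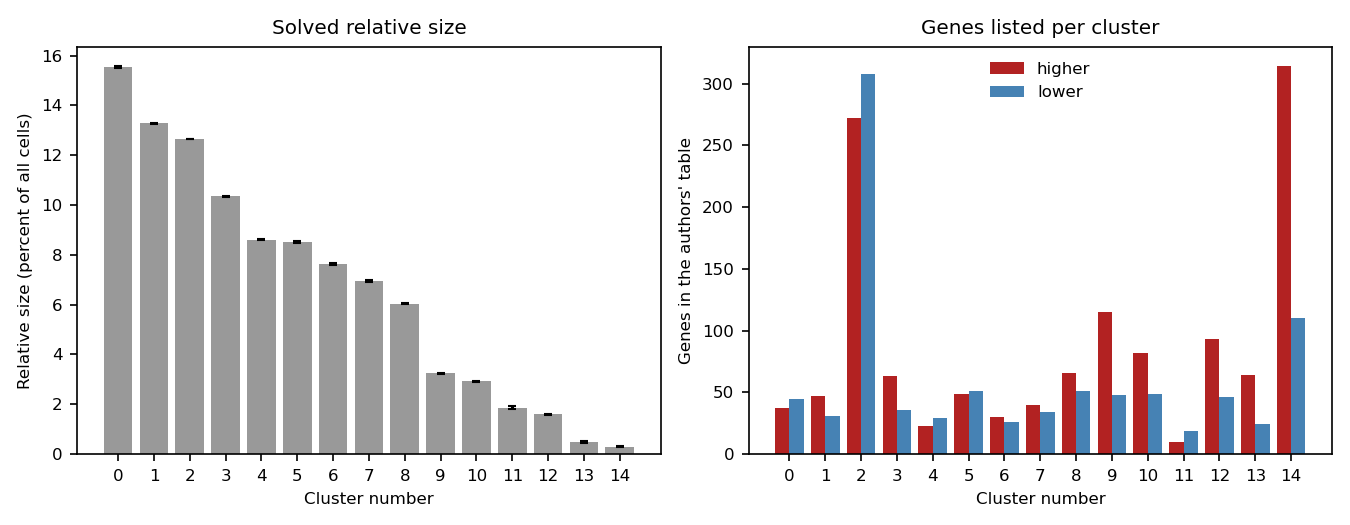
Relative size of the 15 clusters in percent of all cells, with 95% intervals over redrawn genes, and the number of genes the authors' deposited table lists higher (red) and lower (blue) for each. Cluster 0 was the largest at 15.5% of cells, and cluster 2 had both many higher (272) and the most lower genes (308).

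Cluster 2 was cardiomyocyte-like. All 32 genes of the contractile list that were in the table were higher in this cluster, above all random lists. Actc1, the cardiac alpha actin, was 58.9-fold higher in the authors' deposited table and was detected in 98.2% of cells inside against 8.6% outside. The atrial and embryonic myosin light chains Myl7 and Myl4 were 53.5-fold and 40.8-fold higher, and the cardiac troponin Tnnt2 was 35.2-fold higher, in the authors' deposited table. Myh6, Myh7 and Ttn, which encode the myosin heavy chains and the giant spring protein of the sarcomere, were 14.8-fold, 15.6-fold and 20.3-fold higher in the authors' deposited table. Nkx2-5, a cardiac transcription factor chosen after its values were seen, was 5.09-fold higher, and cluster 2 held 88.0% of all cells that detected it, as worked out from the authors' deposited table. The cardiac progenitor list had 5 of 12 members higher here, at percentile 88.5, and was not called.

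Cell cycle genes were lower in cluster 2. All 18 table members of the G2 and M phase list and 6 of 7 of the S phase list were lower. Cenpf and Top2a, which act in chromosome segregation and DNA untangling, were 3.51-fold and 3.34-fold lower in the authors' deposited table. The replication helicase gene Mcm6 was detected in 2.7% of cells inside against 36.8% outside in the authors' deposited table. The S phase call was lost with random lists matched on detection, at percentile 86.1. The imprinted gene Nnat was 11.2-fold lower, Emb 5.86-fold lower and Ptma 5.83-fold lower in the authors' deposited table, the 3 largest falls the naming rule gave.

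Glycolysis and stress genes were higher in cluster 2. Of the 18 glycolysis and hypoxia genes in the table, 14 were higher, including the muscle enolase Eno3 at 4.48-fold, the mitophagy gene Bnip3 at 4.32-fold and the phosphofructokinase Pfkp at 3.66-fold in the authors' deposited table. The stress list had 5 of 9 members higher, with the small heat shock gene Hspb1 at 12-fold and the cell cycle inhibitor Cdkn1a at 3.88-fold in the authors' deposited table. Hspb1 is also abundant in heart muscle. The stress count lay at percentile 96.8, and at 88.9 with matched random lists. Of the 10 mitochondrially encoded genes in the table, 4 were higher, with mt-Co1, chosen after its values were seen, at 2.48-fold in the authors' deposited table.

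Cluster 13 shared the contractile genes of cluster 2 at lower values. It was left unnamed after its values were seen, because fewer of its cells detected these genes and mitochondrial genes were higher beside them. It listed 22 of the 32 contractile genes as higher, above all random lists, and none of them was listed higher in cluster 13 alone. Myl7 was 3.85-fold, Tnnt2 3.52-fold and Myl4 3.42-fold higher in the authors' deposited table. The 22 genes were detected in 26.8% to 67.0% of the cells of cluster 13 and in 56.2% to 99.4% of those of cluster 2, per the authors' deposited table. All 10 mitochondrially encoded genes were higher in cluster 13, with mt-Cytb, a subunit of respiratory complex III chosen after its values were seen, at 3.25-fold in the authors' deposited table. Detection was low there for the size of the fold, with medians of 11.9 and -26.0 percentage points inside minus outside for genes higher and lower by at most 0.75 on the natural log scale, against 24.2 and -17.9 over the 15 clusters. The cytoskeletal genes Tagln2 and Actg1 were 2.18-fold and 2.05-fold lower there in the authors' deposited table. The retinoic acid binding gene Crabp1 and the Wnt antagonist gene Sfrp1 were also lower, so that 2 of the 8 Wnt and retinoic acid genes in the table fell, at percentile 98.9. Of the 79 genes listed for both clusters, 30 were higher in cluster 2 by at least 0.5 on the natural log scale, 10 were higher in cluster 13, and 39 lay within that bound.

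**Figure D2:**
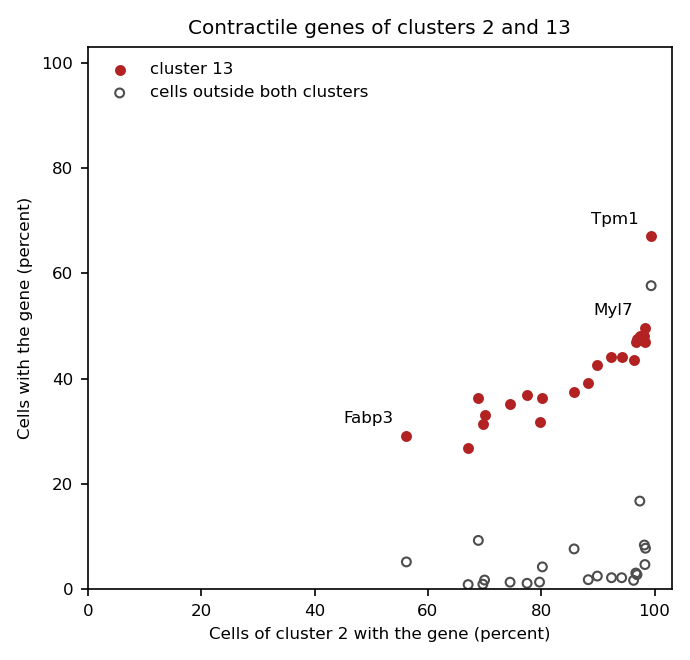
Share of cells that detected each of the 22 contractile genes listed for clusters 2 and 13, in percent: cluster 2 on the horizontal axis, cluster 13 (filled) and cells outside both clusters (open) on the vertical axis, from the authors' deposited table. Cluster 13 lies between 26.8% and 67.0%, below cluster 2 and above the cells outside both.

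Clusters 0 and 7 were nascent-mesoderm-like. Cluster 0 listed 3 of the 11 table members of the primitive streak and nascent mesoderm list as higher and cluster 7 listed 6, at percentile 99.6 and above all random lists. The names rest on these genes only, as 22 of the 33 list genes were not in the table. The streak gene T was listed higher in neither cluster. The neural progenitor list had 2 of 12 members higher in each, Crabp1 and Irx3, at percentiles 94.6 and 94.7, and was not called. Ifitm1, an interferon-induced membrane gene of early mesoderm, was 2.95-fold higher in cluster 0 and 2.63-fold higher in cluster 7 in the authors' deposited table. Cer1, a secreted antagonist of Nodal and BMP, was 1.82-fold and 2.05-fold higher, and Fst, an activin antagonist, was 2.07-fold higher in cluster 0, in the authors' deposited table. Aplnr and Dll3, a receptor and a Notch ligand of early mesoderm, were 2.36-fold and 2.04-fold higher in cluster 7 in the authors' deposited table. Crabp1 led both clusters, at 4.44-fold and 3.06-fold, and Tcf15, a paraxial mesoderm transcription factor, was 3.62-fold and (chosen after its values were seen) 2.38-fold higher, in the authors' deposited table. With only genes listed higher in 1 cluster, cluster 0 kept none of its 3 members. At a natural log fold change of at least 1, cluster 7 fell to percentile 0.

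The retinoic acid genes followed the same clusters. Of 8 Wnt and retinoic acid genes in the table, 2 were higher in cluster 0 and 3 in cluster 7, where Sfrp1 was 2.53-fold higher and Cyp26a1, which degrades retinoic acid, 2.14-fold higher in the authors' deposited table. The inhibitors of differentiation Id1, Id2 and Id3, targets of BMP signalling, were lower in both clusters, with Id2 at 3.64-fold lower in cluster 0 and 3.54-fold lower in cluster 7 in the authors' deposited table. Vim, the mesenchymal intermediate filament, was 3.45-fold and 2.61-fold lower in the authors' deposited table. The smooth muscle and fibroblast list had 3 members lower in cluster 0 (Acta2, Vim, Sparc) and 2 in cluster 7 (Vim, Lgals1). Those calls ended with matched random lists, at percentiles 93.1 and 80.9. In cluster 0 the largest falls were Acta2 at 12.5-fold, Cdkn1c at 6.92-fold and the glycogenin gene Gyg at 6.53-fold, in the authors' deposited table. In a comparison chosen after seeing the data, with cluster 2 taken out of the reference, Acta2 was 3.21-fold and Gyg 1.89-fold lower. The higher lists shared 24 genes, against 1.24 for independent lists, and all 53 genes listed for both clusters lay within 0.5 of each other. Clusters set against all other cells share most of their reference, so part of this overlap may come from it. Genes listed for only 1 of the 2 clusters were not compared, so the 53 genes do not show that the clusters are alike throughout.

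Cluster 8 was pluripotent-like. It listed 5 of the 9 pluripotency genes in the table as higher, above all random lists. Pou5f1, the core pluripotency factor Oct4, was 6.31-fold higher and was detected in 84.1% of cells inside against 7.1% outside in the authors' deposited table. Dnmt3b, a de novo DNA methyltransferase, was 4.41-fold higher, Utf1 2.77-fold and L1td1 2.14-fold, in the authors' deposited table. The kinase gene Pim2 was 4.37-fold higher and Fgf5, a marker of the epiblast, 3.32-fold higher in the authors' deposited table. Epithelial genes were also higher, 4 of 7, with the adhesion genes Epcam at 4.04-fold and Cdh1 at 2.14-fold in the authors' deposited table. Gyg at 6.81-fold, Cdkn1c at 6.41-fold and Mest at 5.74-fold were its largest falls in the authors' deposited table. Gyg was 2.04-fold lower without cluster 2 in the reference.

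Cluster 3 joined genes of 3 lists and was left unnamed. Clusters 1, 8, 9 and 14 also had more than 1 called cell type list and were named. Leaving cluster 3 unnamed was therefore a judgement beyond the rule for cluster names. All 7 epithelial genes in the table were higher, above all random lists, as were 5 of 11 primitive streak genes and 4 of 19 endoderm genes, at percentiles 99.99 and 98.6. These counts are not separate, because Cldn6 is on both the epithelial and endoderm lists and Cer1 on both the streak and endoderm lists. The simple epithelial keratin Krt8 was 8.87-fold higher and the tight junction gene Cldn6 6.08-fold higher in the authors' deposited table. T, the brachyury transcription factor of the primitive streak and notochord, was 8.46-fold higher, and cluster 3 held 75.1% of the cells that detected it, as worked out from the authors' deposited table. Trh, the thyrotropin-releasing hormone gene, was 6.37-fold higher, Krt19 6.04-fold, Foxa2, a factor of endoderm and midline, 2.85-fold, and the Wnt antagonist Dkk1 2.68-fold, in the authors' deposited table. Wnt and retinoic acid genes were higher for 4 of 8, including Sp5, a direct Wnt target, at 2.15-fold in the authors' deposited table. With only genes listed higher in 1 cluster, the epithelial and endoderm counts were both 0 and the streak count lay at percentile 83.7. Clusters 3 and 8 shared 23 higher genes against 3.47 for independent lists, and 32 lower genes against 1.53, of which 20 were left without the genes that cluster 2 lists higher. Pou5f1 was higher in cluster 8, and Cdkn1c, Gpc3, Mest, Cldn6 and Cited2 were higher in cluster 3, by at least 0.5, among 56 genes listed for both.

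Clusters 1 and 4 were neural-progenitor-like. Each listed 4 of the 12 neural progenitor genes in the table as higher, at percentiles 99.9 and 99.99. In cluster 1, Rax, a transcription factor of the eye field and hypothalamus, was 5.97-fold higher and was detected in 71.0% of cells inside against 4.6% outside in the authors' deposited table. Lhx2, a forebrain and eye factor, was 3.57-fold higher, Crabp2 3.10-fold and the neural stem cell factor Sox2 2.05-fold, in the authors' deposited table. Cluster 1 also had 3 of 12 cardiac progenitor genes higher, at percentile 99.1: Tbx3 at 3.26-fold, Fgf10 at 2.67-fold and Bmp4 at 2.43-fold in the authors' deposited table. Each of these 3 is also expressed in tissues other than the heart, and the count fell to percentile 91.2 at a natural log fold change of at least 1. BMP pathway genes were higher for 4 of 9 (Bmp4, Id1, Id2 and Id3), with Id3 at 2.35-fold in the authors' deposited table. Lmo1 was 4.12-fold higher in cluster 1 in the authors' deposited table. Hspa5 and Ccng1, 2 of the 9 stress genes, were 1.76-fold and 1.69-fold lower there in the authors' deposited table. Without cluster 2 in the reference, Ccng1 was 1.31-fold lower and no longer passed the threshold. Hspa5 was not recomputed, as cluster 2 does not list it.

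In cluster 4, the forebrain and patterning genes Otx2 and Lhx5 were each 2.09-fold higher, Fezf2 2.31-fold, Dbx1 2.44-fold and Fgf8 2.49-fold, in the authors' deposited table. The cell cycle gene Ccnd2 was its leading gene, at 2.75-fold in the authors' deposited table. Endoderm genes were higher for 2 of 19, Dkk1 and the nucleolar chaperone gene Npm3, at percentile 95.2, a call that ended with matched random lists, at 92.7. Crabp2 and Dkk1 were also the 2 of 8 Wnt and retinoic acid genes that were higher in cluster 4. At a natural log fold change of at least 1, the neural progenitor members in cluster 4 fell to percentile 0.

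Cluster 6 was left unnamed, as no cell type list was called for it. Its leading genes were Pcp4l1 at 3.40-fold, the trophoblast glycoprotein gene Tpbg at 3.30-fold and Wnt1, a secreted factor of the dorsal midbrain, at 3.06-fold, in the authors' deposited table. Cluster 6 held 74.0% of all cells that detected Wnt1, as worked out from the authors' deposited table. Shh and Foxa2, which mark the ventral midline and were chosen after their values were seen, were 2.21-fold and 1.66-fold higher in the authors' deposited table. Sox2, also chosen after its values were seen, was 2.45-fold higher in cluster 6 and 2.05-fold higher in cluster 1 in the authors' deposited table. It was the only 1 of the 12 neural progenitor genes in the table that cluster 6 listed higher, at percentile 72.7. Clusters 4 and 6 shared 23 lower genes against 0.630 for independent lists. Of these, 12 were left without the genes that cluster 2 lists higher, and part of the overlap may come from the shared reference cells. Of the 31 genes listed for both, 30 lay within 0.5. Npm3 was the exception. In clusters 1, 4 and 6, Crabp1 was lower, at 3.06-fold, 3.59-fold and 3.58-fold, and Sfrp1 at 1.82-fold, 2.15-fold and 2.20-fold, in the authors' deposited table.

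Cluster 12 was neuron-like. It listed 15 of the 17 neuron genes in the table as higher, above all random lists. The neuronal tubulin Tubb3 was 17.5-fold higher and was detected in 74.5% of cells inside against 3.4% outside in the authors' deposited table. Tubb2b was 8.99-fold higher, the microtubule regulator Stmn2 7.99-fold, the proneural factor Neurog2 6.48-fold, Igfbpl1 5.93-fold and Rtn1 5.16-fold, in the authors' deposited table. Tpm1, Myl9 and Gpx3 were its largest falls, at 7.11-fold, 5.35-fold and 4.83-fold in the authors' deposited table. Cluster 2 lists all 3 as higher, and without it in the reference they were 3.14-fold, 1.73-fold and 1.94-fold lower.

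Clusters 5, 10 and 9 carried smooth muscle and fibroblast genes. Clusters 5 and 10 had 4 and 8 of the 13 genes in the table higher, at percentile 99.8 and above all random lists. Cluster 10 was fibroblast-like. Cluster 5 was left unnamed, because the cartilage collagens Col9a1 and Col2a1 were among its leading genes. The fibrillar collagen Col3a1 was 4.30-fold higher in cluster 5 and 8.63-fold higher in cluster 10, and Col1a2 was 3.63-fold and 6.75-fold higher, in the authors' deposited table. Cluster 5 also had the cartilage collagens Col9a1 at 4.56-fold and Col2a1 at 3.88-fold, and the Wnt and BMP antagonist Sostdc1 at 4.68-fold, in the authors' deposited table. Cluster 10 had Lgals1 at 6.13-fold and the opioid precursor Penk at 4.73-fold, with Tbx18 and Postn, an epicardial factor and a matrix gene chosen after their values were seen, at 3.42-fold and 3.24-fold in the authors' deposited table. With only genes listed higher in 1 cluster, cluster 5 kept none of its 4 members. Clusters 5 and 10 shared 30 higher genes against 3.36 for independent lists, and 60 of the 66 genes listed for both lay within 0.5. Igfbp2, Col3a1, Col1a1, Col1a2 and Lgals1 were higher in cluster 10 and Col9a1 in cluster 5 by at least that much.

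Glycolysis genes were lower in clusters 5 and 10, 10 and 8 of 18, above all random lists. The glucose transporter Slc2a1 was 2.73-fold and 2.63-fold lower, and Gapdh was 2.38-fold and 2.13-fold lower, in the authors' deposited table. Cluster 2, which was higher for most glycolysis genes, is part of the reference cells of both. Without it, Slc2a1, Gapdh and Ldha stayed lower in both by at least 0.5 on the natural log scale, as did Aldoa in cluster 5. Bnip3 and Pgk1 in both, Gpi1 in cluster 5 and Aldoa in cluster 10 stayed lower by less. Eno1, Pgam1 and, in cluster 5, Mif were not recomputed, as cluster 2 does not list them. Detection was low in both clusters for the size of the fold. For genes lower by at most 0.75, the median share of cells inside minus outside was -27.6 and -23.7 percentage points, against a median of -17.9 over the 15 clusters. For genes higher by at most 0.75 it was 12.9 and 16.7, against 24.2. In cluster 5, Id1 and Id2, 2 of the 9 BMP pathway genes, were higher, at percentile 95.3. That call ended without ribosomal, mitochondrial and predicted genes, at percentile 94.6.

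Cluster 9 was smooth-muscle or fibroblast-like, with 7 of 13 genes higher, at percentile 99.98. Tagln and Acta2, actin-binding and actin genes of smooth muscle, were 4.18-fold and 3.52-fold higher, Vim 4.10-fold and Sparc 3.63-fold, in the authors' deposited table. Its leading gene was Igfbp7, at 5.53-fold in the authors' deposited table. It also had 4 of 12 cardiac progenitor genes higher, at percentile 97.9. These were Hand1, a transcription factor of heart and extraembryonic mesoderm, at 2.89-fold, Bmp4 at 2.16-fold, Gata6 at 1.90-fold and Isl1 at 1.80-fold in the authors' deposited table. With only genes listed higher in 1 cluster, the smooth muscle and cardiac progenitor counts fell to percentiles 66.1 and 68.0. Of 9 BMP pathway genes, 4 were higher, including the feedback inhibitors Bambi at 4.06-fold and Smad7 at 2.08-fold in the authors' deposited table. Of 9 stress genes, 4 were higher, including Cdkn1a at 3.57-fold in the authors' deposited table, and 3 of 18 G2 and M phase genes were lower.

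Cluster 11 listed 10 higher genes, all of them also higher in another cluster and 8 of them higher in cluster 5. It was left unnamed, since only 2 smooth muscle and fibroblast genes were among them. These were Col3a1 at 2.21-fold and Col1a2 at 2.01-fold in the authors' deposited table. Col2a1 was 2.15-fold, Ccnd2 1.85-fold and the transcription factor Foxd1 1.80-fold higher in the authors' deposited table. Tpm1 at 4.04-fold, Krt8 at 3.87-fold and Myl9 at 3.65-fold were its largest falls in the authors' deposited table. Without cluster 2 in the reference, Tpm1 was 1.78-fold and Myl9 1.17-fold lower. Slc2a1 and Bnip3, 2 of the 18 glycolysis genes, were 2.05-fold and 1.67-fold lower in the authors' deposited table. With cluster 2 taken out, these were 1.88-fold and 1.17-fold lower, and Bnip3 no longer passed the threshold of 0.5.

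Cluster 14, the smallest, was endoderm-like. It listed 14 of the 19 endoderm genes in the table as higher, above all random lists. The basement membrane collagens Col4a1 and Col4a2 were 22.0-fold and 14.1-fold higher, the transthyretin gene Ttr 12.3-fold and the calcium-binding gene S100g 9.22-fold, in the authors' deposited table. Gkn2 at 16.7-fold, Sparc at 16.2-fold and the proteoglycan gene Srgn at 14.4-fold were also among its leading genes in the authors' deposited table. All 4 endothelial and blood genes in the table were higher, at percentile 99.6: Sox17, which is also an endoderm factor, at 6.29-fold, the VEGF receptor Flt1 at 4.87-fold, Egfl7 at 2.83-fold and Ramp2 at 2.03-fold in the authors' deposited table. The other 28 of the 32 genes on that list were not in the table, so this call rests on few of them. Epithelial genes were higher for 6 of 7, at percentile 99.8, with Cldn6 at 4.48-fold and Krt18 at 3.11-fold in the authors' deposited table. Of 18 glycolysis genes, 6 were lower, including Eno1 at 2.53-fold in the authors' deposited table. Without cluster 2 in the reference, Ldha, Aldoa and Gpi1 stayed lower, but by less than 0.5 on the natural log scale. Eno1, Pgam1 and Mif were not recomputed, as cluster 2 does not list them. Of the 10 mitochondrially encoded genes, 3 were higher, with mt-Nd4, chosen after its values were seen, at 1.79-fold in the authors' deposited table.

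Imprinted genes, which are expressed from 1 parental allele, split the clusters. They were higher in cluster 1, for 7 of the 13 in the table, with the cell cycle inhibitor Cdkn1c at 4.22-fold, Mest at 3.14-fold, the transcription factor Plagl1 at 2.39-fold and Nnat at 2.26-fold in the authors' deposited table. They were lower for 5 genes in cluster 0, 7 in cluster 3, 4 in cluster 7, 7 in cluster 8 and 6 in cluster 14, at or above percentile 99.9. Some members went the other way, and none of these counts was called. Igf2 was listed lower in cluster 1 and higher in cluster 0. H19 was higher in clusters 7 and 14, Snrpn in cluster 8 and Peg10 in cluster 14. Cdkn1c was 3.56-fold lower in cluster 3, 5.57-fold lower in cluster 7 and 4.07-fold lower in cluster 14 in the authors' deposited table. The growth factor gene Igf2 was 3.11-fold and 4.11-fold lower in clusters 3 and 8 in the authors' deposited table. In cluster 6, Mest and Nnat were 2.05-fold and 2.19-fold higher, while Meg3 and Igf2 were 1.81-fold and 1.69-fold lower, in the authors' deposited table. Meg3 stayed lower but no longer passed the threshold in clusters 6 (1.60-fold) and 7 without cluster 2 in the reference. Both cluster 6 calls ended with matched random lists, at percentiles 93.3 and 85.8. With only genes listed higher in 1 cluster, the lower calls of clusters 0, 3, 6, 7, 8 and 14 all ended. That filter drops genes such as Mest and Nnat, higher in more than 1 cluster, whatever their fall elsewhere. It therefore does not test those falls.

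Krt8 and Krt18 were lower together in clusters 0, 1, 4, 5, 10, 11 and 12, which were the 2 of 7 epithelial genes listed lower in each. Krt8 was 4.46-fold lower in cluster 5 and 4.10-fold lower in cluster 12 in the authors' deposited table. Cluster 3, with 10.4% of cells, is part of the reference of all 7 clusters. It had Krt8 8.87-fold and Krt18 5.66-fold higher in the authors' deposited table. Part of these falls may therefore come from the reference, and they were not recomputed without cluster 3. With matched random lists, the calls of clusters 0, 1, 5, 10 and 12 ended, at percentiles between 87.1 and 94.8. Id1, Id2 and Id3 were lower in cluster 8 as well, and Crabp1 and Sfrp1 were both lower there. Sparc, Vim and Lgals1 were lower in cluster 3, by 1.68-fold, 2.66-fold and 1.74-fold in the authors' deposited table.

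**Figure D3:**
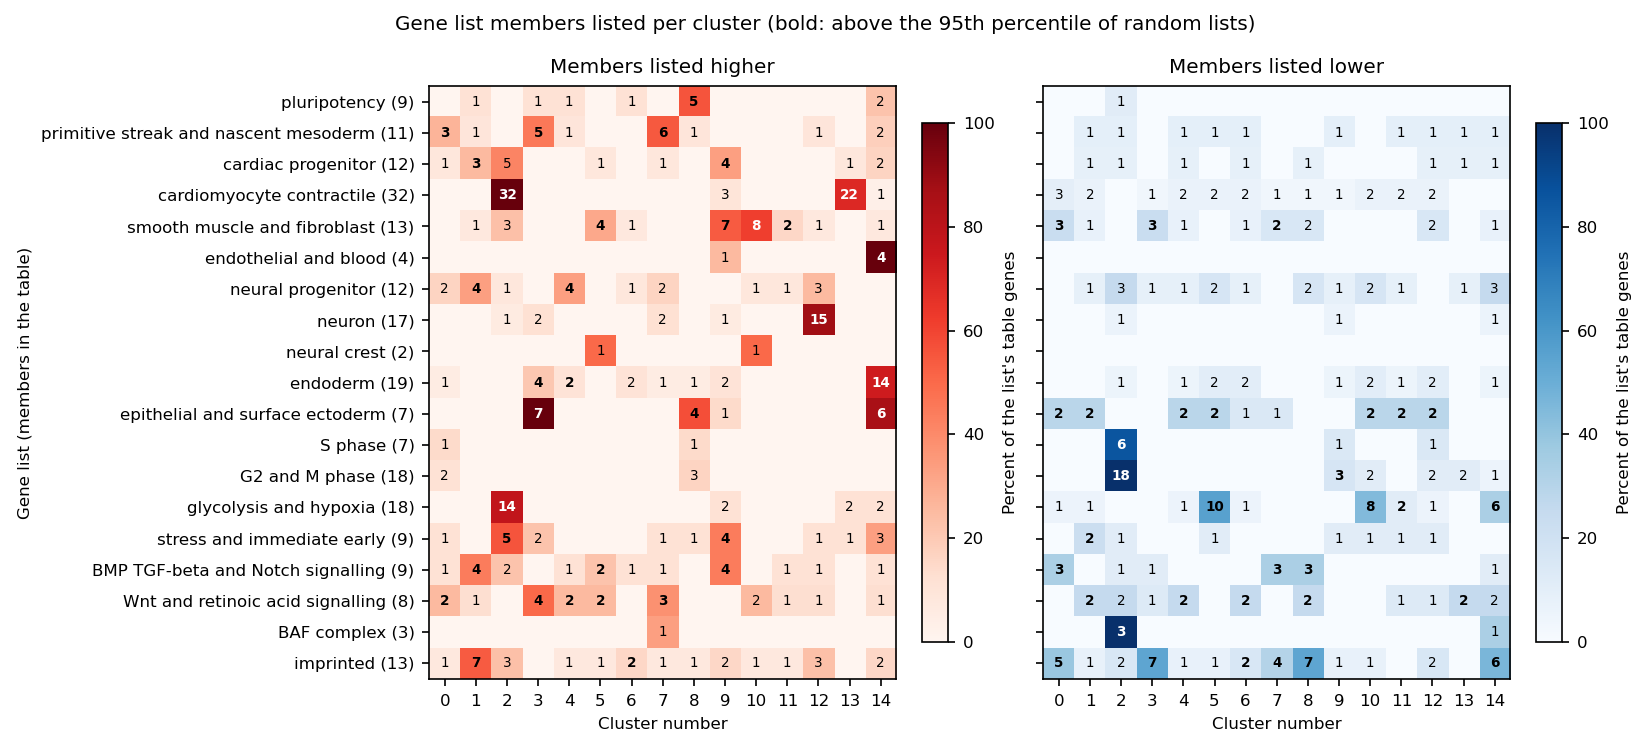
Number of members of each gene list that the authors' deposited table lists higher or lower for each of the 15 clusters, with the colour giving the percent of the list's table genes. Bold numbers lie above the 95th percentile of 10000 random lists. The contractile list has 32 members higher in cluster 2 and 22 in cluster 13.

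The lists differed in how much of them the table held. None of the 27 Hox genes was in the table, and 2 of 15 neural crest genes were, with no call for that list. Only 4 of the 32 endothelial and blood genes were in it. Over the 19 lists with a member in the table, 68 of 570 combinations of list, cluster and direction lay above the 95th percentile, against at most 28.5 by chance, and 45 of the 68 rested on 3 or more members. Percentiles describe this table and are not tests. Of the 68, 9 held under every alternative set before the data were examined that could change them: the contractile and G2 and M phase calls of cluster 2, the endoderm and endothelial calls of cluster 14, the imprinted and neural progenitor calls of cluster 1, and the calls of neuron genes in cluster 12, pluripotency genes in cluster 8 and fibroblast genes in cluster 10. The other 59 ended under at least 1 of them.

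**Figure D4:**
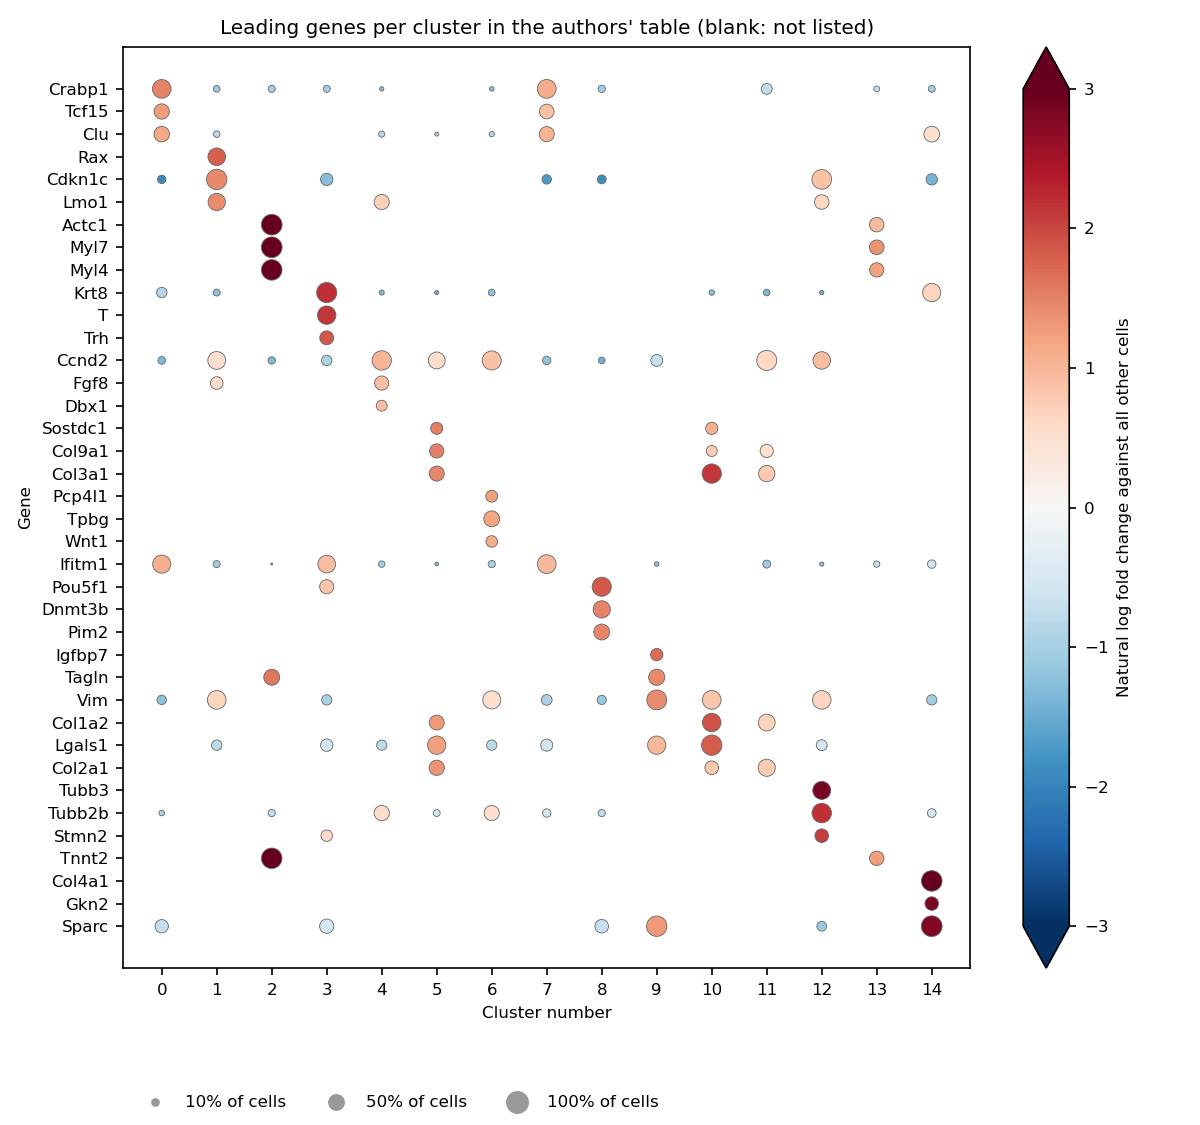
Leading genes of each cluster in the authors' deposited table, with clusters on the horizontal axis and genes on the vertical axis. Colour gives the natural log fold change against all other cells, circle size the percent of the cluster's cells that detected the gene, and a blank means that the gene was not listed. Actc1 in cluster 2 has the highest fold of those named, 58.9-fold.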

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

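Matched random lists, the stricter thresholds, the single-cluster filter, the smaller background, the ranking by share and the 2 other solutions of size were set before the data were examined; the reference without cluster 2 and leaving out its higher genes were chosen after seeing the data. No paired analysis was possible because each group has 1 library and the columns carry no sample. For the same reason both alternatives to the genotype and stage contrasts were not run. A natural log threshold of 0.5 removed no entry, so it tests nothing. Cluster sizes moved by at most 0.0228 percentage points, within their intervals. Of 68 list calls, 9 held under every one of those set beforehand that could change them. These alternatives alter no sign, so a call could end but could not change direction. The causes were not tested, except that fewer genes were counted by construction under the stricter filters. What depth limits is unknown.

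At a natural log fold change of at least 1, the entries fell from 2212 to 508, with 339 higher and 169 lower. Clusters 0 to 14 kept 19, 14, 146, 28, 8, 27, 12, 12, 23, 21, 29, 7, 46, 19 and 97 genes. Of the list calls, 29 ended. The percentile was 0 for streak (cluster 7), smooth muscle and fibroblast lower (3, 7) and higher (11), neural progenitor (4), endoderm (4), G2 and M phase lower (9), glycolysis lower (10, 11, 14), stress lower (1), BMP higher (1), Wnt and retinoic acid higher (3, 4, 5) and lower (13), BAF lower (2) and imprinted higher and lower (6). It was 91.2 and 82.5 for cardiac progenitor (1, 9), 91.0 for epithelial lower (0), 74.9 for S phase lower (2), 94.3 and 87.0 for glycolysis higher (2) and lower (5), 86.5 for stress higher (9), 87.1 and 86.5 for BMP higher (5, 9) and 90.4 for Wnt and retinoic acid lower (8).

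With only genes listed higher in exactly 1 cluster, the entries fell to 840, with 661 higher and 179 lower, and list calls to 31, with 49 of the 68 ended. The filter also drops the lower entries of genes higher in no cluster or in more than 1. The ended lower calls therefore say nothing about those falls. Clusters 0 to 14 kept 18, 22, 203, 27, 9, 31, 18, 10, 45, 51, 52, 3, 70, 9 and 272 genes. The percentile was 0 for streak (0), contractile (13), smooth muscle and fibroblast lower (0, 3, 7) and higher (5, 11), endoderm (3), epithelial higher (3, 8, 14) and lower (0, 1, 4, 5, 10, 11, 12), stress higher (2), BMP lower (0, 7, 8) and higher (1, 5), Wnt and retinoic acid higher (0, 4, 5, 7) and lower (1, 4, 6, 8, 13), and imprinted lower (3, 6, 7, 8) and higher (6). It was 83.7 for streak (3), 68.0 for cardiac progenitor (9), 66.1 for smooth muscle and fibroblast (9), 92.7 for endoderm (4), 76.6 for S phase lower (2), 75.1 for stress higher (9), 74.6 for BMP higher (9), 87.3 for Wnt and retinoic acid higher (3), 89.8 for BAF lower (2), and 90.8 and 75.6 for imprinted lower (0, 14).

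With shares of cells that differ by at least 0.2, lower entries fell from 907 to 533, and clusters 0, 4, 6, 7, 10, 11 and 13 kept 51, 31, 36, 43, 82, 11 and 41 genes. The 17 ended calls were cardiac progenitor (9) at 93.0, smooth muscle and fibroblast lower (3, 7) at 82.4 and 89.0, endoderm (4) at 73.1, epithelial lower (0, 1) at 88.9 and 93.5, G2 and M phase lower (9) at 75.2, glycolysis lower (11, 14) at 0 and 89.4, stress lower (1) at 0, BMP higher (5) at 78.7, Wnt and retinoic acid lower (1, 4, 8) at 92.5, 93.0 and 0 and higher (5) at 81.1, BAF lower (2) at 88.2 and imprinted lower (6) at 88.5.

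With matched random lists, 16 calls ended: smooth muscle and fibroblast lower (0, 7) at 93.1 and 80.9, endoderm (4) at 92.7, epithelial lower (0, 1, 5, 10, 12) at 90.1, 94.8, 87.7, 87.1 and 89.3, S phase lower (2) at 86.1, glycolysis lower (11) at 81.4, stress lower (1) at 94.8 and higher (2) at 88.9, Wnt and retinoic acid higher (5) at 94.2, BAF lower (2) at 91.6, and imprinted higher and lower (6) at 93.3 and 85.8. With an adjusted p-value under 1e-10, clusters 13 and 14 kept 37 and 277 genes, and 3 calls ended: epithelial and glycolysis lower (11) at 93.8 and 84.6, and Wnt and retinoic acid lower (13) at 0. Without ribosomal, mitochondrial and predicted genes, endoderm (4) at 94.85 and BMP higher (5) at 94.6 ended.

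Ranking by share of cells kept 49 of the 75 named higher genes. Without cluster 2 in the reference, 62 of 169 lower entries stayed at or below -0.5 and 7 reversed. On the natural log scale these were Gpx3 at 0.0114 and 0.0603 (0, 5), Gyg at 0.254 (4), Hcfc1r1 at 0.0117 (5), Myl3 at 1.07 (9) and Myl9 at 0.288 and 0.0400 (1, 4). Without the genes cluster 2 lists higher, the 16 genes lower in clusters 0, 3, 7 and 8 fell to 9, and the 16 lower in clusters 1, 4, 6 and 12 to 8. Shared lower genes fell from 29 to 19 for clusters 0 and 7, from 32 to 20 for clusters 3 and 8 and from 23 to 12 for clusters 4 and 6.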

Other observations

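Ccnd2, Emb and Malat1, chosen after their values were seen, split the clusters across their names. Ccnd2, a cyclin that drives entry into S phase, was higher in clusters 1, 4, 5, 6, 11 and 12, by 1.67-fold to 2.75-fold, and lower in clusters 0, 2, 3, 7, 8 and 9 by 1.99-fold to 4.18-fold, in the authors' deposited table. Emb, which encodes the membrane glycoprotein embigin, was 5.05-fold higher in cluster 3, where 99.0% of cells detected it, and 2.07-fold higher in cluster 7, in the authors' deposited table. It was 6.44-fold lower in cluster 5 and 6.14-fold lower in cluster 10 in the authors' deposited table. Malat1, a nuclear long noncoding RNA, was 2.66-fold higher in cluster 2 and 1.82-fold higher in cluster 10, and 2.40-fold lower in cluster 0 and 2.59-fold lower in cluster 7, in the authors' deposited table. Over all 1365 sets of 4 clusters, the most genes listed lower in every cluster of a set was 16, reached by 2 sets. Clusters 0, 3, 7 and 8, with 38.9% of cells, shared lower Cdkn1c, Mest, Nnat and Ccnd2, and clusters 1, 4, 6 and 12, with 31.1%, shared lower Krt8, Emb and Sfrp1. The next highest count was 14. Without the genes that cluster 2 lists higher, the 2 sets shared 9 and 8 and no longer led: clusters 2, 9, 10 and 12 shared 10, a count that leaving out those genes cannot lower, and clusters 0, 7, 8 and 14 shared 8.

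Of the tests below, the one of cluster 2 in the reference and the first test of doublets were fixed before their results were seen, and all others were chosen after the patterns had been seen. No biological explanation was tested for any of the 3 patterns.

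The first pattern was the smaller share of cells of cluster 13 that detected contractile genes. A mixture with 44.1% of cells detecting the genes as cluster 2 does left a root mean square error of 2.97 percentage points over 22 genes, against 7.69 for 1 common lower rate, as shallow cells or free cardiac RNA would give. Those 22 genes had to pass the 25% filter in cluster 13, below which the common rate puts 5 of them, and 10 contractile genes not listed for cluster 13 are left out, of which the mixture puts 2 at 25% or more. Over the 14 of the 22 that cluster 2 detects in at least 80% of cells, none of which the common rate puts under 25%, the errors were 3.34 and 5.25 percentage points. These 14 still had to be listed for cluster 13, which left out 1 such gene, and genes weakly higher there gained little detection, as in shallow cells (median 11.9 percentage points, 24.2 over the clusters), so the mixture and the common rate cannot be told apart. The mixture put 0 of the 22 genes listed lower in both clusters at or below -0.5, so it leaves those lower genes unexplained, and of the mitochondrially encoded genes that could be compared, 100% were higher in cluster 13 than in cluster 2 (4 listed for both, 5 by the threshold that cluster 2 did not pass, 1 not compared), so damaged cells that kept mitochondrial RNA remain a candidate explanation.

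The second pattern was the detection of the genes listed for clusters 5 and 11. Cluster 11 detected 24 of these 25 in more of its cells (median 48.5% against 28.6%). Of the 25, 17 were lower in both clusters, and 7 of the 8 shared higher genes had smaller folds in cluster 11. Higher detection there was thus not limited to genes that mark cluster 5. For genes higher and lower in cluster 11 by at most 0.75, medians inside minus outside were 43.45 and -1.25 percentage points. Over the 15 clusters they were 24.2 and -17.9. Deeper cells of cluster 5 with no other change are argued against: cluster 11 listed 38.1% (16 of 42) of the genes that their level in cluster 5 would put at least 0.75 from 0 on the natural log scale, although 14 of the 17 genes lower in both lay within 0.25 of that level. Doublets of cluster 5 with cluster 1, 4 or 6 were tested first, and cluster 11 listed 31.0% (9 of 29), 38.1% (8 of 21) and 29.6% (8 of 27) of the genes that their mean put past the thresholds, under the bound set beforehand for excluding them. That bound was then judged wrong, because the test put every gene a cluster does not list at the mean of all cells, while the table leaves such a gene anywhere within 0.5. A test added after those results were seen, which counts only genes past the thresholds wherever the unlisted values lie, gave 64.5% (20 of 31) for clusters 4 and 5, the highest of 91 pairs, and 54.5% and 55.9% with clusters 1 and 6, so doublets could not be excluded and were not shown.

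The third pattern was that 169 of the 599 lower entries outside cluster 2 (28.2%), for 42 genes, were of genes that cluster 2 lists higher. Cluster 2 is part of the reference cells of every other cluster, and without it 63.3% of these entries (107) rose above -0.5 on the natural log scale, 7 of them above 0, and 62 stayed at or below -0.5. This met the bound of over 50% that had been set beforehand for the reference as the cause, but crossing the threshold does not mean that the fall was lost. In a test added after that result, the median entry kept 58.2% of its log fold, 69 kept under 50%, and 51 of the 107 kept at least that much. Cluster 2 lists these genes higher, so taking it out had to raise each entry, and only the size of the rise is informative. The reference accounts for part of these falls by construction, and what the rest comes from stays open.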
